A study of Mus musculus with 2 samples.

How the data were processed

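Total RNA (300 ng per library) from the gastrocnemius of 14-day-old female mice was extracted with a Norgen animal tissue kit and sequenced with ERCC spike-ins of a mix labelled for stranded libraries depleted of ribosomal RNA, per the labels. The reads were not used here. For each of the 2 libraries the authors deposited a gene table and a transcript table made from alignments to the transcriptome, and a second transcript table made directly from the reads. The accompanying notes name the mouse assembly mm10 and the GENCODE M21 annotation. The aligner, the quantifiers, their versions and the level of the deposited intervals are not given in the sources used here.

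The gene and transcript tables hold expected counts, which divide a read among the genes it fits and so need not be whole, per the file headers. The same deposited tables hold TPM, abundance corrected for length and scaled to a fixed sum over all listed features, spike-ins included. They also hold a posterior mean TPM, an interval around it that need not hold the TPM value, and a posterior standard deviation of the count. The deposited isoform percent gives each transcript's share of its gene. The second deposited transcript table holds estimated counts and TPM, which were summed per gene and are called the direct quantification. Length minus effective length was 99 bases in the gene tables and 341 bases for long transcripts in the direct quantification. All 55536 gene IDs matched GENCODE M21, from which names, types and mm10 coordinates (first base counted as 1) were taken. A further 26248 rows named only by a number, with 1 count in replicate 1 and 0 in replicate 2, and a phiX row with 1 and 0 counts were left out. Reads of the CAST/EiJ alleles were measured against a C57BL/6J reference, and any loss of them was not measured.

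Gene counts summed to 35592003 and 42105856, and spike-ins to 285877 and 317175 with 74 and 76 of 96 having a read. A gene with 0 counts allows up to 3. Expected counts were rounded to whole numbers for tests. Library sizes were scaled with TMM in edgeR 4.0.16 (factors 0.954 and 1.05), which also gave the common coefficient of variation of the 2 libraries as 1 group. DESeq2 1.42.0 gave size factors for an alternative. R 4.3.3, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 were used.

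With 1 library on each side, edgeR's quasi-likelihood test has no residual degrees of freedom. Each gene with a summed count of at least 20 was therefore tested with a two-sided exact binomial test of its counts, with Benjamini-Hochberg adjustment, and called at an adjusted p under 0.05 and a change of at least 2-fold. Log2 ratios of replicate 2 over replicate 1 are of TMM-scaled counts, unless another scaling is named, with a prior count of 0.5. Their 95% intervals are exact binomial (Clopper-Pearson). A small ratio can differ in sign from the change in TPM, which is scaled differently. A gene shares reads where the deposited posterior standard deviation exceeds 1% of its count in either library, which does not tell a copy from an overlapping gene. The median log2 ratio of each gene list with at least 3 tested members was set against 10000 random lists of the same size matched on mean expression in 10 groups, and stood apart outside their central 95%. The test was run on simulated counts for 15748 genes at the depth of these 2 libraries, with 50 genes for each fold. It called 100% of 3-fold and 4-fold changes, 96% of 0.25-fold changes, 0% of 1.5-fold changes and 0% of unchanged genes. These counts were drawn with counting error only, and the changed genes from those with an expected summed count of at least 50. The share of unchanged genes called therefore says nothing of false calls between libraries that differ beyond counting error. A coefficient of variation of 0.2 simulated as 1 group was recovered as 0.198 over 15697 genes.

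Gene lists, pairs, isoform genes, tests, alternatives and the rule for named genes were fixed before the data were examined. The rule takes all members of the myosin lists and the pairs, the 3 members of highest mean TPM of every other list, the 20 nuclear coding and 10 non-coding genes of highest mean TPM, the 10 largest rises and 10 largest falls among called genes, Xist and the Y-linked genes, and set isoform genes. Some genes it takes are not reported here. Other names were chosen after their values were seen, among them Ryr1, Dmd, Mstn, Pax7, Myog, Myod1, Fkbp5, Sln, the genes of largest change with few shared reads and the further called members of lists. Of 677 listed symbols, 2 had no ID in M21. Where 1 symbol had several IDs, that of highest mean TPM was used. Shares of TPM are of the sum over all genes, without spike-ins, unless another base is named. Pairs were compared per library, a difference counting as larger than the error where the deposited intervals did not overlap in either library. The alternatives were the direct quantification, posterior mean TPM, TPM over nuclear genes, CPM, other minima and pseudocounts, other library scalings, and each library alone. Alternatives chosen after seeing the data were TPM over nuclear protein-coding genes, genes with few shared reads only, the mitochondrial share with nuclear copies counted, and removal of a trend in transcript length and GC content. Marker lists describe RNA in bulk tissue and give no cell shares.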

Results

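Total RNA was sequenced from the gastrocnemius, a fast-contracting calf muscle, of female B6CASTF1/J mice at 14 days of age. These mice are first-generation hybrids of the C57BL/6J and CAST/EiJ strains. The series held 2 libraries, replicates 1 and 2 of 1 group, so no treatment, age or tissue was compared and the values below describe this muscle and the agreement of its 2 libraries. The labels call the libraries biological replicates. Both library descriptions name 3 females, while the text for the tissue sample repeats this for replicate 1 and names a female in the singular for replicate 2, so whether each library came from 1 animal or a pool was not clear. Any spread between the libraries may then be technical as well as between animals. The gene tables held 35877882 expected counts in replicate 1 and 42423031 in replicate 2. Values are given as replicate 1 and replicate 2, or as mean ± SD (n = 2). Intervals and p-values cover counting error only, and with 1 library on each side no p across animals exists.

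Of the nuclear protein-coding genes, Acta1, skeletal muscle alpha-actin, was highest at 29222 ± 1529.7 TPM, followed by Mylpf, the fast regulatory myosin light chain, at 27141 ± 1759.9 TPM and Ckm, muscle creatine kinase, at 16699 ± 59.6 TPM. Myl1, Myh4, Tpm1 and Tnnt3 followed at 14640.3 ± 516, 11885 ± 450.5, 11202 ± 799 and 10861 ± 56.4 TPM. Pvalb, the calcium buffer parvalbumin, stood at 9532 ± 1103 TPM, Atp2a1, the fast-fibre calcium pump, at 8333 ± 559 TPM and Tnnc2, fast troponin C, at 7226 ± 629 TPM. These 10 genes held 14.9% ± 0.626 of the TPM of all genes, spike-ins left out, 24.1% with the second deposited quantification and 30.0% of the TPM of nuclear protein-coding genes. In the second quantification TPM of the genes detected in the gene tables was a median of 1.33 times that in the gene tables (quartiles 1.23 and 1.52). There Myl1 lay above Ckm, at 28172 against 26454 TPM, and Gapdh above Pvalb, at 13362 against 11485 TPM. The 3 highest members or their order differed in 15 of the 40 gene lists with at least 3 members, so the orders below are those of the gene tables. In the gene tables the next 10 nuclear protein-coding genes were Tnni2, Aldoa, Gapdh, Tpm2, Eno3, Casq1, Actc1, Actn3, Neb and Pygm, from 6775 ± 89.4 TPM for Tnni2 to 2071 ± 156 TPM for Pygm. A TPM of at least 1 in both libraries was reached by 11959 annotated genes, of which 11017 were protein-coding, 373 processed pseudogenes and 131 lincRNAs. Acta1 lies on chromosome 8, 123891769 to 123894751, minus strand of mm10, and Mylpf on chromosome 7, 127208890 to 127214298, plus strand.

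Among the 10 sarcomeric myosin heavy chain genes, the fast genes Myh4, Myh1 and Myh2 held 95.6% ± 1.56 of the summed TPM. Myh4, which encodes the heavy chain of type IIb fibres, alone held 76.1% ± 2.10, against 13.2% ± 2.76 for Myh1 (type IIx) and 6.27% ± 0.901 for Myh2 (type IIa). Myh7, the slow heavy chain, held 2.61% ± 1.06, or 1.71% with the second quantification, which put Myh1 at 4253 against 2056 TPM, and the developmental pair Myh8 (perinatal) and Myh3 (embryonic) held 1.27% ± 0.321. Myh8 was measured at 147 and 211 TPM and Myh3 at 13.6 and 24.0 TPM. Of the remaining sarcomeric genes, Myh6, the alpha-cardiac heavy chain, stood at 63.2 and 104 TPM, Myh13 at 2.85 and 1.95 TPM and Myh7b at 0.800 and 0.700 TPM, and Myh15 was listed at 0 TPM in both. The fast share was 96.7% and 94.5% and the slow share 1.86% and 3.36%, so the order fast, slow, developmental was the same in both libraries, and the fast share lay above the others by more than the spread between them. The fast genes Myh4 (ENSMUSG00000057003.12; chromosome 11, 67238029 to 67260446, plus strand), Myh1 (chromosome 11, 67200052 to 67224575, plus strand) and Myh2 (chromosome 11, 67171027 to 67197517, plus strand) lie beside Myh8 (chromosome 11, 67277124 to 67308634, plus strand), Myh3 (chromosome 11, 67078300 to 67102291, plus strand) and Myh13 on chromosome 11. Myh7 (chromosome 14, 54970684 to 54994626, minus strand) and Myh6 are neighbours. Of the non-sarcomeric heavy chains, Myh9 stood at 48.1 ± 8.31, Myh14 at 9.61 ± 0.601, Myh11 at 9.54 ± 1.34 and Myh10 at 9.43 ± 2.53 TPM.

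**Figure D1:**
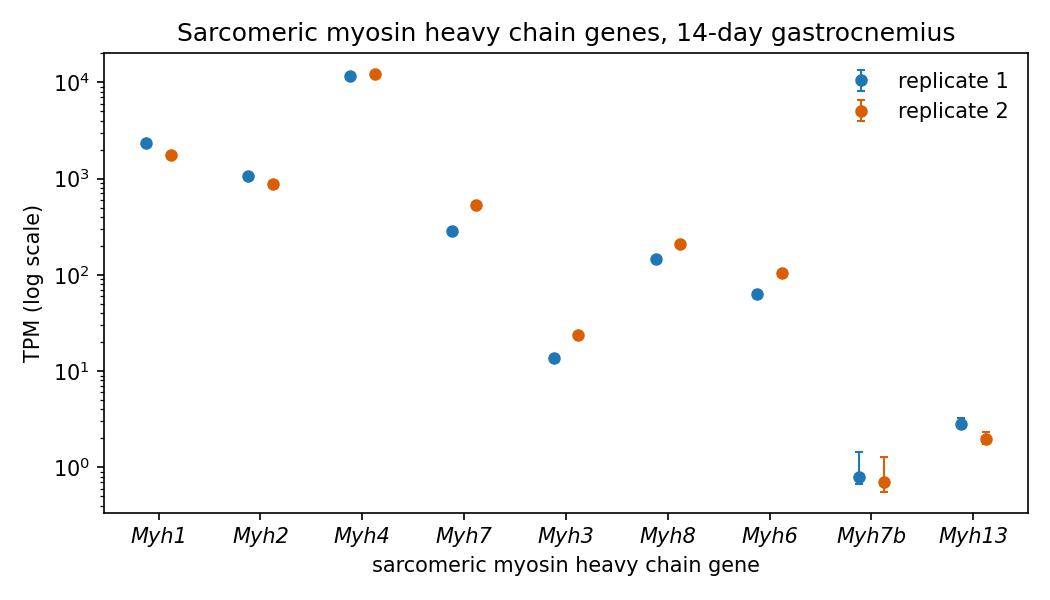
TPM on a log axis of the 9 sarcomeric myosin heavy chain genes with a mean above 0.05 TPM, replicate 1 in blue and replicate 2 in orange, with bars to the bounds of the deposited intervals, which belong to the posterior mean and can lie to 1 side of the point. Myh4 stands highest in both libraries at 11567 and 12204 TPM, and Myh7 reads 288 and 528 TPM.

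In both libraries the gene listed as fast was higher than the gene listed as slow in all 10 pairs of isoform genes. The largest mean difference was between the calcium pumps Atp2a1 and Atp2a2, with a log2 ratio of 6.06 ± 0.53. The calsequestrins Casq1 over Casq2 gave 5.87 ± 0.08, and in replicate 2 exceeded the calcium pumps, at 5.92 against 5.68 for Atp2a1 over Atp2a2. The light chains Mylpf over Myl2 gave 5.82 ± 0.43 and the tropomyosins Tpm1 over Tpm3 5.67 ± 0.49. The troponins gave 5.59 ± 0.51 for Tnni2 over Tnni1, 5.49 ± 0.58 for Tnnt3 over Tnnt1 and 5.12 ± 0.49 for Tnnc2 over Tnnc1. The smallest differences were Myoz1 over Myoz2 at 2.44 ± 0.05, Actn3 over Actn2 at 1.79 ± 0.21 and Mybpc2 over Mybpc1, which stood 2.60-fold and 3.10-fold apart. The deposited intervals of the 2 genes did not overlap in either library for any of the 10 pairs. With the second quantification Mylpf over Myl2 gave 5.11. The ratio was narrower in replicate 2 for 7 pairs, among them all 3 troponin pairs, and wider for Casq1, Actn3 and Mybpc2.

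Adult isoform genes were higher than their developmental counterparts in all 9 pairs and in both libraries. Chrne, the acetylcholine receptor subunit of mature junctions, exceeded the fetal subunit Chrng by a log2 ratio of 5.17 ± 0.90. Chrng held only 28 and 48 counts, at 0.37 and 0.83 TPM, so the size of this ratio is uncertain. The log2 ratio was 11.15 ± 0.30 for Myl1 over Myl4, 10.52 ± 0.67 for Ckm over Ckb, 9.92 ± 0.39 for Tnnt3 over Tnnt2 and 9.36 ± 0.52 for Myh4 over Myh3. It was 6.07 ± 0.31 for Myh4 over Myh8 and 4.90 ± 0.45 for the glucose transporters Slc2a4 over Slc2a1. Acta1 over Actc1, the cardiac actin, was the closest pair at 3.20 ± 0.14, with Actc1 at 3186 ± 465 TPM. With the second quantification Acta1 over Actc1 gave 3.82 and Slc2a4 over Slc2a1 4.32. All 9 ratios were narrower in replicate 2, and no pair of deposited intervals overlapped.

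In all 9 pairs the listed muscle form of a metabolic enzyme or subunit was higher than the listed general form. Pfkm, muscle phosphofructokinase, was 217-fold and 155-fold higher than Pfkl in replicates 1 and 2, and Pgam2 was 155-fold and 125-fold higher than Pgam1. Eno3 over Eno1 gave 22.1-fold and 15.7-fold, Ldha over Ldhb 14.7-fold and 23.3-fold, Hk2 over Hk1 9.94-fold and 5.41-fold and Cpt1b over Cpt1a 10.6-fold and 9.97-fold. For the cytochrome oxidase subunits the folds were 11.8-fold and 9.87-fold for Cox6a2 over Cox6a1, 9.66-fold and 7.59-fold for Cox8b over Cox8a and 1.86-fold and 1.67-fold for Cox7a1 over Cox7a2. The ratio was narrower in replicate 2 for 8 pairs and wider for Ldha over Ldhb. With the second deposited quantification, and with read counts not divided by length, 8 of the 9 pairs kept this order, and Cox7a1 over Cox7a2 did not. The second quantification gave 0.866-fold for this pair, 6.86-fold for Cox6a2 over Cox6a1 and 11.2-fold for Ldha over Ldhb, and read counts in replicate 2 were 3895 for Cox7a1 and 4093 for Cox7a2. Eno1 and Pgam1 share reads with other genes, so their values are uncertain.

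**Figure D2:**
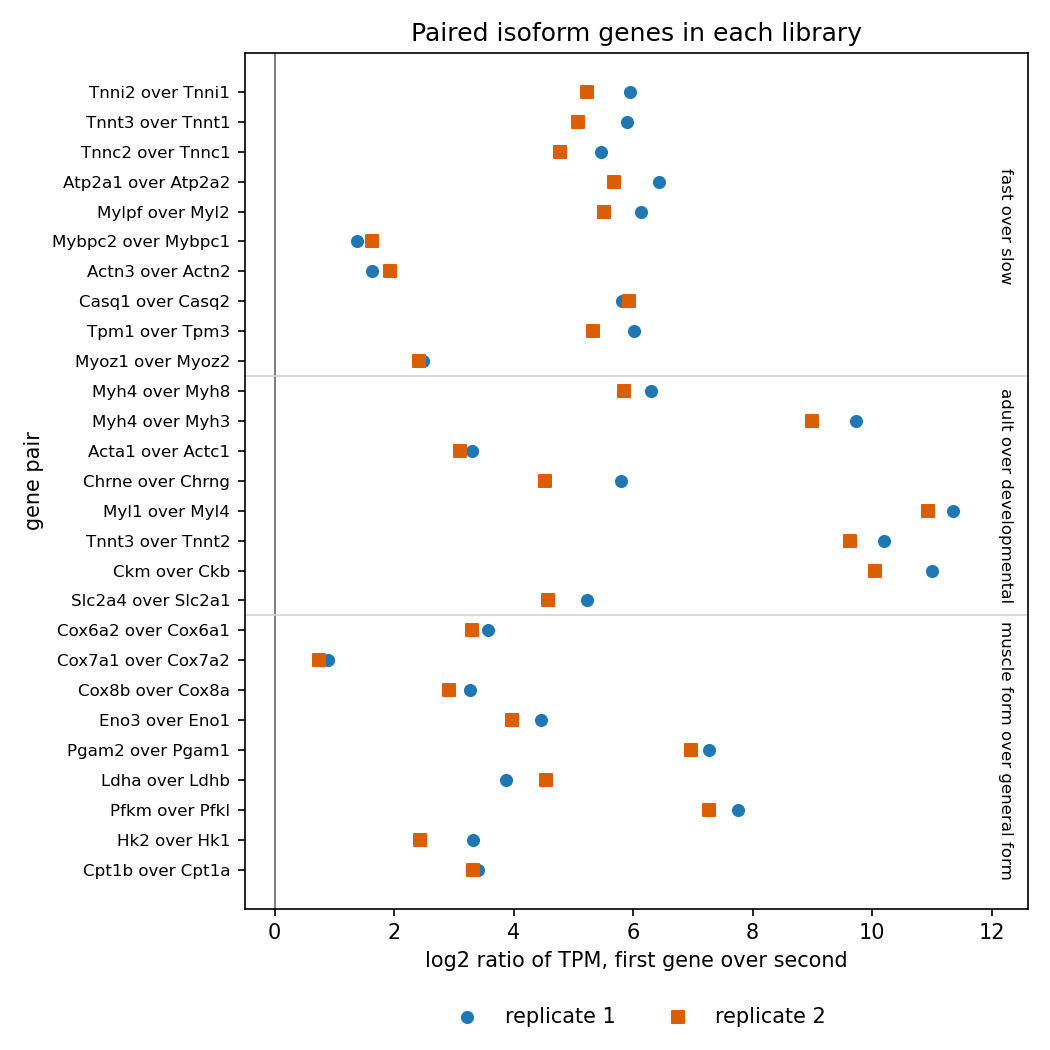
Log2 ratio of TPM, first gene over second, for gene pairs of the 3 sets in replicate 1 (circles) and replicate 2 (squares). Every point drawn lies above 0, from Cox7a1 over Cox7a2 at 0.74 in replicate 2 to Myl1 over Myl4 at 11.36 in replicate 1.

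All 43 sarcomere genes with an identifier reached 1 TPM in both libraries, led by Acta1, Mylpf and Myl1, and Neb and Ttn, which encode the giant proteins nebulin and titin, stood at 2119 and 2149 and 1963 and 2041 TPM. Of the excitation-contraction coupling list, 28 of 29 genes reached 1 TPM, led by Pvalb, Atp2a1 and Casq1 at 3261 ± 229 TPM, while Ryr1, the calcium release channel, stood at 388 ± 34.5 TPM. All 21 genes of the dystrophin complex list were detected, with Dag1 at 108 ± 11.4 and Sgca at 107 ± 2.88 TPM, and Dmd itself at 47.8 ± 2.86 TPM.

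Genes of glycolysis, of which 17 of 18 reached 1 TPM in both libraries, and of oxidative phosphorylation, all 75 detected, were both abundant. The 18 glycolysis genes summed to 21637 ± 456 TPM and the 75 nuclear oxidative phosphorylation genes to 26883 ± 2110.3 TPM, a ratio of 0.807 ± 0.0463. From read counts without division by length this ratio was 1.40, on the other side of 1. Aldoa, Gapdh and Eno3 led glycolysis at 6164 ± 614, 4632 ± 16.2 and 3284 ± 17.4 TPM, though with the second quantification Gapdh lay above Aldoa, at 13362 against 8098 TPM. Atp5b, Atp5a1 and Atp5g3, subunits of ATP synthase, led the oxidative list at 1907 ± 182, 948 ± 92.7 and 868 ± 86.2 TPM. Pygm, glycogen phosphorylase, led the glycogen list at 2071 ± 156 TPM, which also held Ugp2 at 129.7 ± 1.73 TPM. Mdh2 and Sdhc of the citric acid cycle stood at 531 ± 39.4 and 344 ± 9.58 TPM. The 13 mitochondrially encoded coding genes held 4.56% ± 0.412 of the TPM of all genes, with mt-Co1 at 10859 ± 1245, mt-Cytb at 6190.4 ± 587 and mt-Nd1 at 5113 ± 331 TPM. This share and the order of the genes are uncertain, since mt-Co2, mt-Co3 and mt-Atp6 share reads. Nuclear copies such as Gm10925 and Gm28437 may hold part of those reads, but which genes share them was not measured. The share was 6.36% with the second quantification, where the copies Gm28661 and Gm28437 still held 17861 and 10067 TPM. It was 7.70% in the gene tables with Gm28661, Gm10925 and Gm28437 counted, a choice made after the values were seen. The neighbouring pseudogene Gm29216, at 4423 ± 592 TPM in the gene tables, was not counted. The second quantification put mt-Atp6 at 14754 TPM, above mt-Cytb at 8593. In the gene tables mt-Atp6 stood at 3487 ± 424 and mt-Co2 at 123 and 80.9 TPM. Fatty acid oxidation was led by Fabp3, Pdk4 and Etfb at 462 ± 197, 398 ± 345 and 186 ± 27.4 TPM.

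The regulators of muscle identity were present at moderate levels. Nfix, Mef2c and Myf6 led the myogenic list at 257 ± 26.3, 149 ± 28.5 and 65.9 ± 13.8 TPM, and Myog and Myod1 stood at 35.8 ± 1.32 and 14.5 ± 0.665 TPM. In the satellite cell and myoblast list, Itga7, Sdc4 and Dbn1 reached 42.7 ± 4.83, 22.8 ± 1.17 and 14.9 ± 4.80 TPM, and Pax7, the satellite cell transcription factor, 2.09 ± 0.608 TPM. The neuromuscular junction list was led by Prkar1a, Chrnb1 and Ache at 90.8 ± 8.68, 36.5 ± 4.06 and 25.9 ± 4.50 TPM. How much of this RNA came from junctions was not measured. Proliferation genes were low, with Pcna, Top2a and Mki67 at 13.6 ± 1.46, 7.33 ± 1.28 and 5.51 ± 0.997 TPM. Matrix genes were high, with Col1a1 at 1543 ± 587, Col3a1 at 947 ± 266 and Col1a2 at 898 ± 313 TPM. Of the growth and atrophy genes, Igf2 stood at 1388 ± 352, Igfbp5 at 144 ± 19.8 and Fstl1 at 122 ± 28.1 TPM, and Mstn, myostatin, at 16.9 ± 1.18 TPM.

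Markers of several resident cell types were detected, and 78 of the 107 listed for cells of the muscle and its surroundings reached 1 TPM in both libraries. All 11 fibro-adipogenic markers did, led by Col1a1, Col3a1 and Dcn at 216 ± 36.6 TPM, as did all 11 endothelial markers, led by Cdh5, Pecam1 and Egfl7 at 65.7 ± 0.552, 44.4 ± 0.912 and 35.5 ± 5.95 TPM. Mural and smooth muscle markers reached 1 TPM for 9 of 10, led by Acta2, Rgs5 and Abcc9 at 213 ± 132, 106 ± 2.05 and 60.8 ± 1.88 TPM. All 11 Schwann cell markers were detected, among them the myelin genes Pmp22 and Mbp at 119 ± 64.7 and 97.8 ± 63.7 TPM. All 8 tendon markers were detected, led by Fmod, Thbs4 and Tnmd at 82.5 ± 23.2, 58.2 ± 7.33 and 35.5 ± 11.3 TPM. All 10 macrophage markers were detected at low levels, with Lyz2 at 15.9 ± 0.120, Mrc1 at 11.2 and 12.8 and Csf1r at 7.58 and 11.3 TPM. Erythroid genes were led by Hbb-bs, Hba-a1 and Hba-a2 at 800.4 ± 376, 734 ± 331 and 587 ± 269 TPM, of which the alpha-globin pair share reads. Adipocyte markers reached 1 TPM for 7 of 10, led by Fabp4 at 159 and 122, Cfd at 6.96 and 8.09 and Lipe at 7.66 and 5.54 TPM. Granulocyte and mast cell markers did for 4 of 10, with Cma1, Cpa3 and Mcpt4 at 3.65 ± 1.65, 3.12 ± 1.01 and 2.81 ± 0.841 TPM, and bone and cartilage markers for 1 of 8, Col2a1 at 8.91 ± 3.58 TPM, with Sox9 and Acan at 1.23 ± 0.488 and 0.910 ± 0.354 TPM. None of 10 lymphoid markers did, the highest being Ptprc, Cd79b and Cd4 at 0.735 ± 0.0778, 0.475 ± 0.0778 and 0.170 ± 0.0566 TPM.

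The background lists, for tissues outside the sample, were mostly near 0. Of 6 liver genes none reached 1 TPM in both libraries, with Alb, Cyp2e1 and Apoa1 at 43 and 3, 22 and 5 and 9 and 1 counts. Of 8 keratinocyte genes 1 did, Krt10 at 2.73 ± 0.0849 TPM, with Dsp and Lor at 0.0200 ± 0.0141 and 0.0200 ± 0 TPM. Of 8 neuronal genes 2 did, Slc17a7 and Map2 at 1.79 ± 0.424 and 1.68 ± 0.410 TPM, with Gad1 at 0.395 ± 0.375 TPM. Of 8 heart genes 3 did, Actc1, Myh6 and Tnnt2 at 11.4 ± 3.03 TPM, genes that developing skeletal muscle also uses, while Myl7, Nppa and Nppb were listed at 0 TPM in both.

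In the gene tables, though not in the second quantification, small structured RNAs were among the most abundant non-coding transcripts, beside mitochondrial ribosomal RNA. Rn7s1 and Rn7s2, near-identical copies of the 7SL RNA of the signal recognition particle, each stood at 126952 ± 2470.1 TPM and together held 25.7% ± 0.509 of the TPM of all genes. Their reads are shared, so the split between them carries no information. The second quantification gave them 1 and 2 counts each, Rn7sk 0 in both libraries and Rpph1 3 and 1, and was led by mt-Rnr2 at 78393 and mt-Rnr1 at 42822 TPM. The mitochondrial ribosomal RNAs mt-Rnr2 and mt-Rnr1 stood at 55159 ± 7263 and 33546 ± 3763 TPM, and Rn7sk, the 7SK RNA, at 16727 ± 1635 TPM. Gm28661, Gm10925 and Gm28437, nuclear copies of mitochondrial genes on chromosome 1, stood at 12543 ± 961, 9953 ± 686 and 8468 ± 544 TPM. Each shares reads, possibly with the mitochondrial genes. The second quantification left Gm10925 631 and 207 counts, against 170006 and 178223 in the gene tables. The other copies kept most of theirs, with 163113 and 165391 counts for Gm28661 and 117942 and 123069 for Gm28437. Gm26917 followed at 6898 ± 749 and Rpph1, the RNA of ribonuclease P, at 4612 ± 238 TPM. Among imprinted genes, the maternally expressed H19 (ENSMUSG00000000031.16; chromosome 7, 142575529 to 142578143, minus strand) was highest at 4342 ± 142 TPM, then Igf2 (chromosome 7, 142650766 to 142666816, minus strand) and Gnas at 794 ± 51.9 TPM. Alleles of the 2 parental strains were not analysed here. Xist, which marks the inactive X chromosome, stood at 21.8 and 23.0 TPM, and the 4 Y-linked genes Ddx3y, Uty, Eif2s3y and Kdm5d together held 2 counts in each library, and no more than 0.0200 TPM per gene.

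Transcript choice was shared by the libraries for most genes. Of the 45 genes listed for isoforms, all above 1 TPM and among them the lincRNA Neat1, 42 had the same most abundant transcript in both. Tpm1-205 made up 97.2% and 97.3% of Tpm1, Atp2a1-201 95.8% and 93.7% of Atp2a1, Ldb3-207 75.8% and 73.7% of Ldb3, and Pkm-202 54.7% and 52.8% of Pkm. Tnnt3 was divided among many transcripts, the leading Tnnt3-224 holding 27.5% and 30.5%. The 3 genes whose leading transcript differed were Ttn, Tnnt1 and Camk2d. By the second deposited quantification these 3 had the same leading transcript in both libraries, as did 41 of the 45 in all, and Camk2g, Ppargc1a, Rps24 and Gnas differed. Ttn was led by Ttn-205 in replicate 1 at 26.31% and by the short Ttn-215 in replicate 2 at 25.97%, where Ttn-205 held 25.65%, and Tnnt1 by Tnnt1-201 at 34.1% and Tnnt1-203 at 31.7%. Camk2d was led by Camk2d-206 at 37.0% and by the short retained-intron transcript Camk2d-217 at 34.3%. The second deposited quantification named the same leading transcript for 34 of the 45 genes in each replicate. It differed in both for Tnnt3, Tnnt1, Pkm, Capzb, Myl1, Trdn and Igf2, among others, in replicate 1 for Ppargc1a, Rps24 and Gnas, and in replicate 2 for Ttn, Camk2d and Camk2g. For Tnnt3 it gave Tnnt3-225 57.7% and 50.2%, so the isoform shares of these genes depended on the quantification. Shares could also differ where the leading transcript was the same. The second quantification gave Tpm1-205 75.7% and 74.8% of Tpm1, while Atp2a1-201 at 97.6% and 95.3% and Ldb3-207 at 72.9% and 70.8% were close.

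The 2 libraries were close for most genes and differed beyond counting error for many. Across 12839 genes with at least 1 TPM in either library, Pearson's r of log2(TPM + 1) was 0.980 and Spearman's rho 0.975, across genes, which are not independent replicates. Of the 6322 genes with a summed count of at least 1000, 95.05% lay within 1.5-fold. The common biological coefficient of variation estimated by edgeR was 0.159. A chi-square statistic of 50.7 per degree of freedom over the tested genes shows that they are not copies of 1 library. The ERCC spike-ins, synthetic RNAs added in known amounts, held 0.797% and 0.748% of expected counts. The 15 spike-ins with at least 1000 reads differed between libraries by an SD of 0.06 on the log2 scale, against 0.29 for genes with a summed count of that size.

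Of the 37 gene lists with at least 3 tested members, 19 had a median log2 ratio of replicate 2 over replicate 1 outside the range of matched random lists, 10 low and 9 high in replicate 2. The random lists hold unrelated genes, while members of 1 list may vary together between any 2 libraries and some lists share genes, so the number expected without a change is not known. Scaling on spike-in totals added 0.23 to every log2 ratio, and so to the list medians and their random ranges alike, and the same 19 lists stood apart. Genes induced by glucocorticoids and fasting had the largest median shift, and all 17 of the list were lower in replicate 2. Of these, 12 were called over all genes. In every list the numbers called over all genes and adjusted over the list alone were the same. The median log2 ratio was -1.69, where matched random lists lay at -0.15 to 0.09. Pdk4, which restrains glucose oxidation, fell from 641 to 154 TPM, a log2 ratio of -2.20 (95% interval -2.22 to -2.17). Sgk1 stood at 192 and 67.0 TPM (-1.69), Fkbp5, a classical glucocorticoid receptor target, at 20.9 and 4.49 TPM (-2.23; adjusted p = 9.46e-228, exact binomial test) and Tsc22d3 at 106 and 57.9 TPM (-1.09). With libraries scaled on spike-in totals, Tsc22d3, Klf15 and Angptl4 of the 12 were no longer called. Ddit4 stood at 38.3 and 7.49 TPM, the metallothioneins Mt2 and Mt1 at 50.8 and 9.84 and 31.9 and 9.08 TPM, and Fbxo32, a ubiquitin ligase of muscle atrophy, at 24.4 and 8 TPM. Of 28 fatty acid oxidation genes all were lower in replicate 2 and 3 were called, Pdk4, Ucp3 (-1.27) and Fabp3 (-1.07), with a median of -0.61, though Fabp3 was not called with spike-in scaling. The same direction, with no member called, was seen for all 23 citric acid cycle genes (median -0.39), all 75 nuclear oxidative phosphorylation genes (-0.32), all 13 mitochondrially encoded genes (-0.32) and 12 of 13 glycogen genes (-0.30). With spike-in scaling these medians were -0.16, -0.09, -0.10 and -0.07, and that of fatty acid oxidation -0.38. Of the 18 circadian genes, Per1 (-1.83), Per2 (-1.23) and Nfil3 (-1.05) were called lower and Nr1d1 (1.31) higher in replicate 2, while Tef, Nr1d2 and Bhlhe40, the most abundant at 54.4 ± 7.31, 23.6 ± 0.276 and 23.6 ± 1.85 TPM, were not called. The median of the circadian list, -0.00, lay inside the random range, and Nfil3 was not called with spike-in scaling.

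Schwann cell genes were higher in replicate 2 for all 11 members, with a median log2 ratio of 0.95 against -0.19 to 0.17 for matched random lists. The 5 called included Mbp, from 52.8 to 143 TPM (1.29, 1.23 to 1.36), Pmp22 (1.05), Prx (1.01) and Egr2 (1.00), of which Prx and Egr2 were not called with the second quantification. Connective tissue lists lay on the same side, with medians of 0.33 for 33 matrix genes, of which 31 were higher in replicate 2, 0.19 for the fibro-adipogenic list, 0.46 for the tendon list, and 0.66 for the bone and cartilage list, where Acan was called (1.03). No matrix, tendon or fibro-adipogenic gene was called, and Col1a1 stood at 1128 and 1958 TPM. Of the mural list, with a median of 0.14 that no longer stood apart at 0.12 with a length and GC trend removed, Acta2 (1.18) and Cnn1 (1.41) were called higher. The satellite cell list had a median of 0.14, which no longer stood apart with the second quantification (0.05) or among genes with few shared reads. Medians were 0.45 for the heart list and 0.18 for the imprinted list, where Mirg was called (1.12) and Rian and Meg3, non-coding RNAs of the same chromosome 12 cluster, stood at 173 and 365 and 107 and 197 TPM. Of the excitation-contraction list Sln, sarcolipin, an inhibitor of the calcium pump, was called at 1.25 and 8.18 TPM (2.52; adjusted p = 1.86e-38, exact binomial test). With spike-in scaling the Schwann cell, matrix, fibro-adipogenic, mural, satellite, heart and imprinted medians were 1.18, 0.56, 0.42, 0.37, 0.37, 0.67 and 0.41. The genes listed as slow members of the 10 pairs went both ways and none was called. Tnnc1 (0.70), Tpm3 (0.64), Tnnt1 (0.64), Myl2 (0.59), Tnni1 (0.58) and Atp2a2 (0.45) had positive ratios, and Mybpc1 (-0.40), Actn2 (-0.39), Myoz2 (-0.17) and Casq2 (-0.15) negative ones, of which Myoz2 and Casq2 turned positive with the spike-in shift. Myh7 stood at 0.69, not called.

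Haemoglobin and red cell genes were lower in replicate 2, with 6 of 7 tested members of the erythroid list called and a median of -1.17. Hbb-bs stood at 1066 and 535 TPM and Alas2, the haem synthesis enzyme of red cells, at 16.9 and 8.27 TPM. With spike-in scaling Hba-a1, Hba-a2, Hbb-bs and Alas2 were no longer called, and the median was -0.94. The endothelial list had a median of -0.21 with no member called. With the spike-in shift it read 0.017 and still lay below its random range, 0.05 to 0.34. The fast myosin list, with Myh4 at -0.09, Myh1 at -0.58 and Myh2 at -0.44, and the list of other sarcomeric myosins (-0.42) each had 3 tested members and a median below the random range. In the latter Myh13 (-0.71) and Myh7b (-0.42) were lower and Myh6, its most abundant member, higher (0.63), none called. With spike-in scaling the medians of these 2 lists were -0.22 and -0.19. Myh4, the most abundant fast gene, rose in TPM, from 11567 to 12204, although its ratio of TMM-scaled counts was below 0. Both liver genes tested, Alb (43 and 3 counts) and Cyp2e1 (22 and 5 counts), were called lower in replicate 2. Of the immediate early and stress genes, 6 were called higher and 2 lower in replicate 2, with a median of 0.06 inside the random range. Hspb1, Jund and Nr4a1 were the most abundant at 148 and 224, 32.2 and 42.6 and 30.1 and 14.9 TPM. Of these Nr4a1 was called (-1.19), as were Egr1 (1.60) and Fos (1.12), and with spike-in scaling Nr4a1 and Zfp36 were not. Called members of other lists included Tcap (-1.09) of the sarcomere, Mcm5 (1.18) of the proliferation, S100a9 (-1.87, 15 and 5 counts) of the granulocyte and mast cell and Gad1 (1.88, with shared reads) of the neuron list. Usp18 (2.51) was called higher and Rsad2 (-1.15) lower in the interferon list. With spike-in scaling neither Tcap nor Rsad2 (-0.92) was called. Medians of the sarcomere (-0.12), excitation-contraction (-0.00), dystrophin complex (0.01), glycolysis (-0.16), myogenic (-0.07), junction (0.01), proliferation (0.12), growth and atrophy (-0.03), non-sarcomeric myosin (0.12), macrophage (0.04), lymphoid (-0.02), granulocyte and mast cell (0.45), adipocyte (-0.08), neuron (0.31), non-coding (-0.06) and interferon (-0.01) lists lay inside the random range. With spike-in scaling, which raised every ratio, 10 of the medians inside that range, the circadian one included, changed sign, and the sarcomere and glycolysis medians were 0.10 and 0.07. The interferon list was low, with Irf1 and Bst2 at 4.26 ± 0.0354 and 3.85 ± 0.948 TPM.

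**Figure D3:**
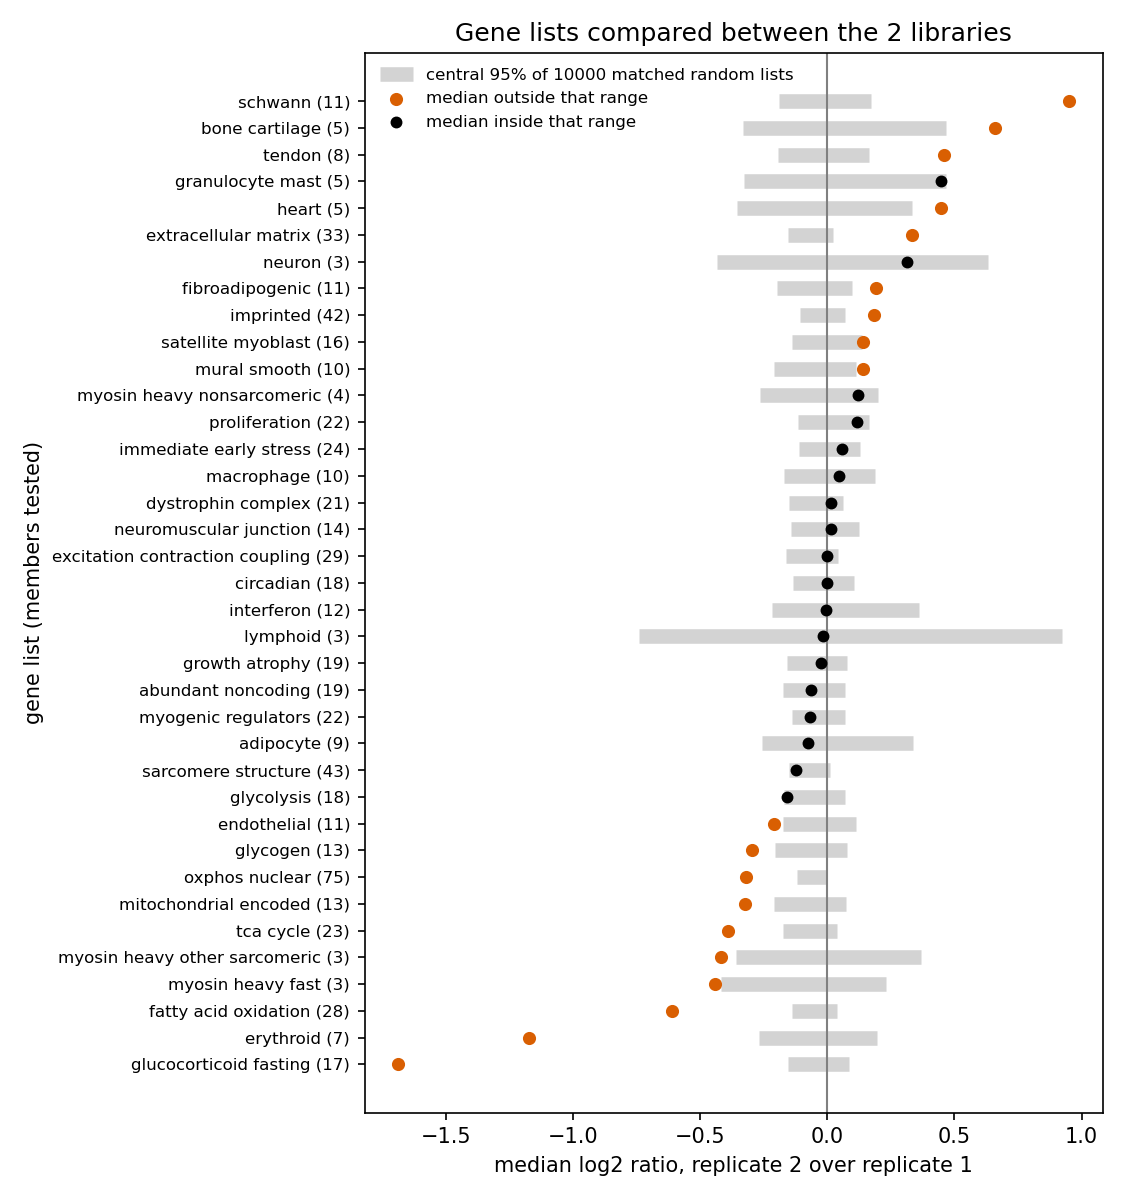
Median log2 ratio of replicate 2 over replicate 1 for the 37 gene lists with at least 3 tested members (members tested in brackets), with the central 95% of 10000 expression-matched random lists as grey bars. Orange medians lie outside that range, from -1.69 for the glucocorticoid and fasting list to 0.95 for the Schwann cell list.

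Over all 15734 genes tested, 277 were called higher and 258 lower in replicate 2, by a two-sided exact binomial test with Benjamini-Hochberg adjustment and a change of at least 2-fold. The test compares the reads of these 2 libraries, not a condition. Scaling on spike-in totals gave 573 higher and 156 lower, and scaling on total counts 412 and 195, because they moved the median log2 ratio of all tested genes to 0.23 and 0.14. Among genes with a summed count of at least 200, 79 were called higher and 97 lower. The 10 largest falls and 10 largest rises all shared reads with other genes, by the deposited error of their counts, and are uncertain. That limit was met by 1906 of the 15734 tested genes, but by 29 of the 36 with at most 2 counts in a library, as these 20 have. The falls were the pseudogenes Gm10335, Gm10259, Gm13597, Gm6565, Rpl30-ps9 and AC134468.1, the small RNAs Rnu3a and Gm22042, and the coding genes Gm45062 and Gm45234, each with at most 1 count in replicate 2. The rises were the pseudogenes Gm6361, Gm10132, Gm10145, Gm12191 and Gm2274, and the coding genes 1700047I17Rik2, Gm20388, Gm9803, Gm49369 and Gm20708, each with at most 2 counts in replicate 1. In the second quantification 13 of the 20 had too few counts to be tested, and 1 of the other 7, Gm45062, was called the same way. Among genes with few shared reads and a summed count of at least 200, chosen after the values were seen, the largest falls were Arrdc2 at 31.2 and 2.35 TPM (-4.07), Depp1 (-2.78), Gadd45g (-2.75), Slc25a25 (-2.67) and Chac1 (-2.57), and the largest rises Sln, Sqle (1.86), Vat1l (1.65) and Egr1.

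**Figure D4:**
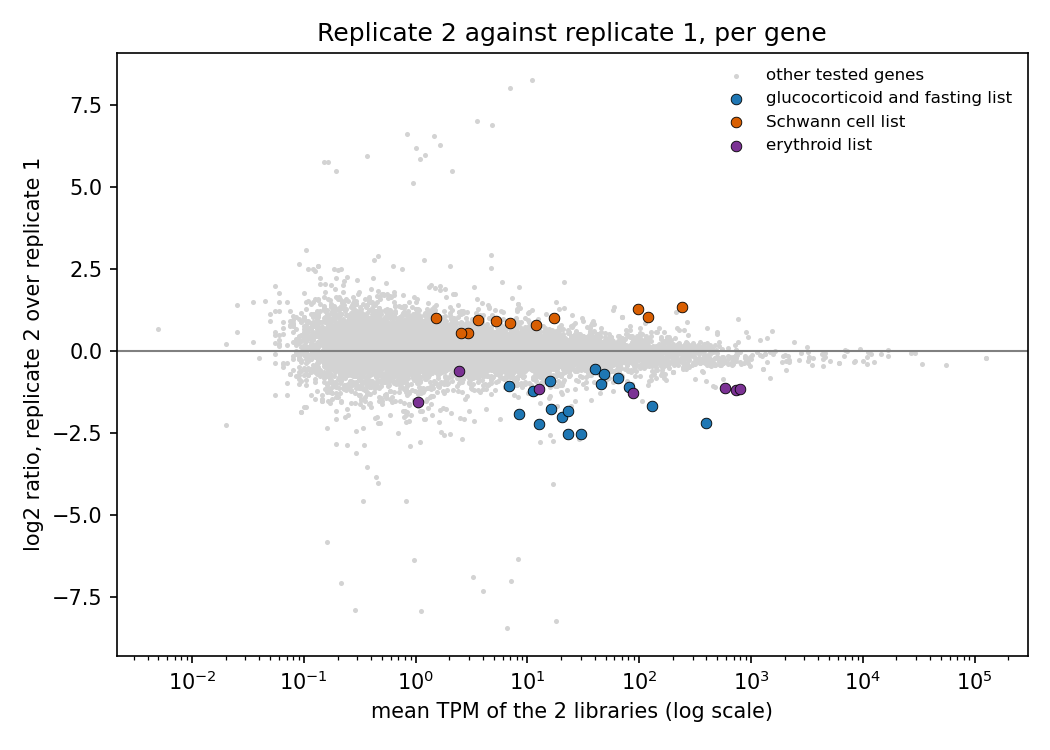
Log2 ratio of replicate 2 over replicate 1 against mean TPM (log axis) for each tested gene, with the glucocorticoid and fasting list in blue, the Schwann cell list in orange and the erythroid list in purple. The blue points lie below 0, Pdk4 at -2.20, and the orange points above it, Mbp at 1.29.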

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

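The tests on genes with few shared reads, on TPM over nuclear protein-coding genes, with nuclear copies of mitochondrial genes counted and with the length and GC trend removed were chosen after the data were seen. Where the quantification or unit was changed, 10 fast over slow and 9 adult over developmental pairs were again counted, and 8 of 9 muscle over general pairs with the direct quantification and with CPM. With the direct quantification the Myh4 share was 70.1%, glycolysis over oxidative phosphorylation 0.859, the mitochondrial share 6.36%, the top 10 share 24.1% and the spike-in share 0.568%. With CPM the ratio of glycolysis to oxidative phosphorylation was 1.40, the mitochondrial share 3.31% and the top 10 share 16.5%. The top 10 share was 17.2% over nuclear genes and 30.0% over nuclear protein-coding genes, as a smaller denominator gives, and the spike-in share was 1.29% of TPM. A minimum of 5 TPM left 7406 genes detected, by construction. The replicate correlation was 0.956 with a pseudocount of 0.1 and 0.993 without a filter, and a summed count of at least 200 left 176 genes differing, from fewer tested genes. With 3 nuclear copies counted the mitochondrial share was 7.70%, by construction. For the other changes the cause was not tested. Shares of TPM in the direct quantification also have a different base. The 92 genes with a summed count of at least 1000 and under 5% of it there held 32.3% of the gene TPM of the gene tables.

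With 2 libraries each lies within 1 SD of their mean by construction, so leaving 1 out says nothing about stability. Alone they gave, for example, 1.86% and 3.36% for the slow myosin share.

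Spike-in scaling moved all list medians and random ranges by the same amount, so the endothelial median reversed to 0.017 and 10 medians inside the range changed sign by arithmetic, while the same 19 lists stood apart. With the direct quantification Gm45234 reversed to 0.13 and Gm20388 to -5.36, as did 1 of 2 genes named Nnt (to -0.33), all with shared reads. Of the named genes called, 13 of 90 were no longer called with spike-in scaling, 6 of 90 with total counts, 1 of 90 with the length and GC trend removed and none with DESeq2 size factors, all with the same sign. With the direct quantification 8 of 76 tested were not called, Gm45234 and Nnt with the sign reversed and the others with the same sign. Over all genes, tested there or not, the direct quantification called 328 of the 535 called genes in the same direction, among 481 calls. The satellite cell list no longer stood apart with the direct quantification or with genes of few shared reads, nor the mural list with the length and GC trend removed, while the granulocyte and mast cell and the immediate early lists did with the direct quantification. The correlation cannot be computed without a replicate, nor the mitochondrial share over nuclear genes. No paired analysis was possible because there is 1 group. The share, pair and isoform results come from no test. Depth limits genes near 20 counts, and 1.5-fold changes lie below the 2-fold limit by design.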

Other observations

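The test behind the gene calls, the glucocorticoid, sarcomere, Schwann and endothelial lists and spike-in scaling were planned. The length and GC correction, the further Schwann cell and myelin genes and the tests of lost RNAs were added after the data were seen. What each explanation predicts was written after the result was seen, except for Schwann cell genes outside myelin.

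Sqle and Cyp51, enzymes of sterol synthesis picked after their values were seen, were called higher in replicate 2. Sqle held 48 and 229 counts (log2 ratio 1.86) and Cyp51 93 and 283 (1.22). Hmgcs1 of the same route was not called, at 0.49, and no list of the route was tested. Myl6b, a myosin light chain of slow fibres, was called at 30.6 and 87.7 TPM (1.35), beside Myl3 at 213 and 337 TPM (0.49) and Tpm3 at 164 and 293 TPM (0.64), which were not called. Myh2, the heavy chain of oxidative type IIa fibres, was not called either, at -0.44. Mybpc1 (-0.40) and Actn2 (-0.39), listed as the slow members of their pairs, were not called. Whether Mybpc1 and Actn2 are restricted to slow fibres was not tested. Tcap, the titin cap of the Z-disc, was the 1 sarcomere gene called, at 623 and 328 TPM (-1.09), though not with spike-in scaling (-0.87).

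All 17 glucocorticoid and fasting genes were lower in replicate 2, with a median log2 ratio of -1.69. After a trend in transcript length and GC content was subtracted the median was -1.68, outside the range of matched random lists (-0.15 to 0.09), and the trend accounted for an R2 of 0.00370 over the genes, which argues against such a bias as the whole cause. Less muscle fibre RNA in replicate 2 would lower sarcomere genes as far, but their median was -0.12 (quartiles -0.22 and -0.01), and 0.10 with spike-in scaling. The labels give no feeding state, time of dissection or handling, so no biological explanation was tested, and a difference in any of these, or between single and pooled animals, stays open.

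Schwann cell genes were higher in replicate 2, with a median of 0.95. It was 0.96 after the same length and GC correction. A lower share of muscle fibre RNA would raise the markers of every other cell type alike. The endothelial median, however, was -0.21, with an upper quartile of -0.07 below the Schwann lower quartile of 0.83. With spike-in scaling the endothelial and Schwann medians were 0.017 and 1.18. Medians of other cell lists went from -1.17 for erythroid to 0.66 for bone and cartilage markers, with tendon at 0.46 and macrophage at 0.04. The rise was thus not uniform, but a part played by a lower share of fibre RNA stays open. More nerve tissue in replicate 2 is a candidate explanation, since 7 Schwann cell genes outside myelin, listed before their values were seen, had a median of 0.56 against -0.26 to 0.36 for random lists, the most abundant being Erbb3 at 2.86 and 3.49 and Scn7a at 1.36 and 1.84 TPM, neither called, and 8 further myelin genes 0.87. Some of these genes are also used outside Schwann cells, and myelin advancing with age was not separated from more nerve. Both libraries are labelled 14 days, and all 9 adult over developmental ratios were narrower in replicate 2, but those pairs hold no myelin genes.

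Short structured RNAs that led the gene tables were near 0 in the direct quantification. Rn7sk held 101623 and 134886 counts in the gene tables and 0 in both direct tables, and Rpph1 held 27498 and 34191 against 3 and 1. Shared reads are not the whole cause, since 16 genes with few shared reads and a summed count of at least 1000 had a direct count under 5% of that in the gene tables. The length of the transcripts may account for the loss, since the direct quantification subtracted 341 bases from long transcripts, and of the 12 such genes whose transcripts were all shorter than that, 100% were lost, against 0.0674% of the 5939 others. Of the 371 genes of that count with shared reads, 76 were lost, all 35 short ones, Rn7s1 and Rn7s2 included, and 41 of 336 longer ones, so shared reads stay open there. The 92 lost genes together held 5.24% of the gene-table counts and 32.3% of its gene TPM, so the TPM of the remaining genes is scaled differently in the direct quantification.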
